A study of Mus musculus with 2 samples.

How the data were processed

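RNA sequencing of mouse liver was deposited for 2 libraries, 1 from mice given a β-Gal adenovirus and 1 from mice given a GBP5 adenovirus, grouped by the virus named in the labels. Per the labels' protocols, livers were frozen, total RNA was extracted with TriPure and libraries were made with Illumina protocols and sequenced on an Illumina instrument. The protocols also name viruses with fragments of GBP5, residues 1 to 306 and 307 to 586, which were not analysed here. The deposited values are FPKM, fragments scaled by transcript length and library total, per gene, and per the submitters' processing notes TopHat2, HTSeq 0.6.1 and the GRCm38 assembly were used. The annotation release, the strand setting, the treatment of reads with several matches and the program that made the FPKM are not given in the sources used here. FPKM divides by the total of each library, so a few very abundant genes can shift all others.

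Each table held 47442 features in the same order, of which 47069 had Ensembl identifiers and 373 were unnamed new loci. Symbols, positions and biotypes came from GENCODE M21, on the same GRCm38 assembly, by identifier, for 46488 features. The features without a match held 0.131% of FPKM in the β-Gal library and 0.129% in the GBP5 library. Older list symbols were matched through RefSeq synonyms, and 2 of 691 list symbols, Lilr4b and Ust4r, stayed unmatched.

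Reads were recovered from the FPKM. The product of FPKM and the mean length of a gene's annotated isoforms came in whole multiples of a single step, which gave about 18405000 assigned reads in the β-Gal library and 17206000 in the GBP5 library. Within a tolerance of 0.02 reads, 80.7% of values under 50 reads in the β-Gal library and 82.6% in the GBP5 library were whole, and 51.6% and 51.2% of all values above 0. A gene whose isoforms differ between GENCODE M21 and the annotation the authors used does not come out whole. FPKM levels computed with a mean isoform length are raised for genes with short isoforms, so levels of different genes should not be compared closely, whereas ratios of a gene between libraries do not depend on length. Intervals are exact (Clopper-Pearson) 95% intervals of the FPKM ratio given the sum of both read numbers, and were computed only for genes with whole reads in both libraries. Where such a gene had 0 reads in a library, the ratio was computed against a floor of 3 reads, which is not a confidence limit, and the exact 95% limit, which is lower, is given beside it; other genes at 0 are given as listed at 0.

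The ratio of the libraries was log2 of (GBP5 FPKM + 1) over (β-Gal FPKM + 1), for features with at least 1 FPKM in either library, and a feature was called higher or lower at a log2 ratio of at least 1 or at most -1. With 1 library per group no test was made. For each gene list with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size, drawn with replacement from 20 bins of mean expression, and a percentile under 2.5 or over 97.5 was said to stand apart. These percentiles describe the 2 libraries and are not p-values. Folds given for single genes are plain FPKM ratios, whereas counts of genes past 2-fold use the size rule, with the pseudocount.

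The ratio, the filter, the size rule, 34 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule took Gbp5, Gbp2, Gbp3 and Gbp7, the 8 highest and 8 lowest genes by log2 ratio other than predicted models, pseudogenes and immunoglobulin or T-cell receptor segments, the 3 members with the largest absolute log2 ratio of each biology or cell type list, 2 of each technical list, and Alb, Tnf, Il1b, Il6, Ccl2, Nlrp3, Casp1, Cyp7a1 and Saa1. It gave 114 genes, of which 2 are not reported here. Pseudogenes were recognised by symbol and also by their annotated biotype, a detail set after the data were seen. The lists cover interferon-inducible, inflammatory, cell death, acute-phase, metabolic, cell cycle and stress genes, markers of immune and liver cells, and technical lists for sex-biased, circadian, erythroid, pancreatic, immediate early, mitochondrial and ribosomal protein genes. A further 5 lists, for pancreatic islet genes, p53 targets, fetal liver genes, cytoskeleton genes and proteasome subunits, were written after the data were seen. Of these, the islet genes alone had not yet been looked at.

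Alternatives were pseudocounts of 0.1 and 5 FPKM, no filter, a filter of 5 FPKM, rescaling of the GBP5 library by the median ratio of 11828 genes, rescaling of both libraries to the same sum (TPM), equal sums without the 50 most abundant genes, and protein-coding genes only. Counts without pseudogenes and counts after rescaling by 40 ribosomal protein genes were added after the data were seen. The procedure was tested on simulated reads for 46488 genes, with 200 genes of at least 5 FPKM changed 4-fold and the others at parity. All 100.0% of those higher and 100.0% of those lower were recovered, and 0.64% of unchanged features passed the size rule by counting error. Recovery of changed genes below 5 FPKM was not simulated, nor was the median log2 ratio of 0.48 of the real libraries. Of 100 random lists of 20 genes, drawn from all simulated genes past the filter, the changed ones included, 9 fell outside the percentile limits. A list near a limit should therefore be read with care. Those simulated lists were of unrelated genes, so they do not calibrate real lists whose members may move together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.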

Results

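The series compared liver transcripts of mice labelled C57BL/6, aged 8 to 9 weeks, 10 days after an adenovirus was injected into the tail vein. In the control group the virus carried β-galactosidase (β-Gal), a bacterial enzyme with no known role in the liver, and in the other group it carried GBP5, a guanylate-binding protein. Guanylate-binding proteins are GTPases that interferon induces and that take part in defence against microbes. Each group held 1 RNA sequencing library, and the number of animals behind a library is not given in the sources used here. The strain was taken from the labels, and a difference in strain between the libraries could not be separated from that of the virus. The question, as the title of the series states it, was whether raised GBP5 in the liver is followed by liver damage and inflammation. The steps of the FPKM values correspond to about 18405000 assigned reads in the β-Gal library and 17206000 in the GBP5 library. Of 47442 features, 19974 were above 0 in the β-Gal library and 21021 in the GBP5 library, and 12317 and 13110 reached 1 FPKM. There were no replicates, so no p-value is given, and "higher" and "lower" describe the GBP5 library relative to the β-Gal library. Intervals are 95% intervals of the FPKM ratio of these libraries and cover counting error only, since reads copied by PCR are not independent molecules.

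The GBP5 library differed from the β-Gal library across much of liver function. Most measured cell cycle, oxidative stress and interferon-inducible genes and most markers of T and NK cells were at least 2-fold higher in it, although after rescaling by the median ratio fewer than before passed 2-fold, among them 12 of 28 type I interferon genes and 8 of 22 T and NK cell markers. Most listed plasma protein, cytochrome P450, acute-phase and neutrophil genes were at least 2-fold lower, before and after rescaling. Bile acid, lipid synthesis and cholesterol synthesis genes had medians below 0, with 7 of 19, 7 of 19 and 7 of 22 members at least 2-fold lower (10, 14 and 15 after rescaling). Of 13599 features with at least 1 FPKM in either library, 2605 were at least 2-fold higher with GBP5, 756 were at least 2-fold lower and 10238 were neither, on the scale of log2(FPKM + 1), which understates the change of low genes. Most genes lay above parity: the median log2 ratio of all 13599 features was 0.48, and among 11828 genes with at least 1 FPKM in both libraries the median FPKM ratio was 1.45. Rescaling the GBP5 library by that median left 958 features higher and 1276 lower, so that 42.9% of the features past 2-fold were higher, against 77.5% as deposited. The 50 most abundant genes held 34.2% of all FPKM in the β-Gal library and 23.9% in the GBP5 library, and albumin (Alb) alone held 9.76% and 5.96%. With equal sums without these 50 genes, 1922 features were still higher and 865 lower, with a median log2 ratio of 0.36. At larger sizes the balance was closer, with 331 features at least 4-fold higher and 204 lower, and 71 at least 8-fold higher and 74 lower. Of 34 gene lists fixed in advance, 15 had a median ratio above, and 14 below, the central 95% of random lists matched on expression, and 5 lay within it. Members of a list may move together between livers, which random lists do not reproduce, so this tally is a description only.

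**Figure D1:**
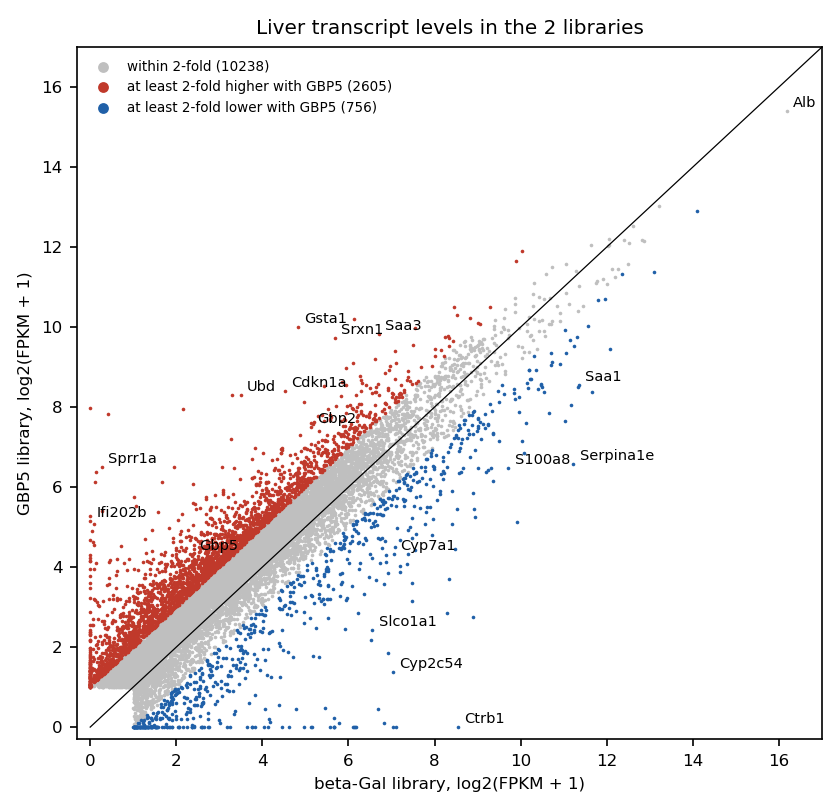
Each point is 1 of 13599 features with at least 1 FPKM in either library, at its log2(FPKM + 1) in the β-Gal library (x axis) and in the GBP5 library (y axis), 1 library each. The line marks equal levels, red points are the 2605 features at least 2-fold higher with GBP5 and blue points the 756 at least 2-fold lower; after rescaling by the median ratio these were 958 and 1276.

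Mouse Gbp5 (ENSMUSG00000105504, chromosome 3, 142493978 to 142522344, plus strand, GRCm38) was at 4.24 FPKM in the β-Gal library and 19.1 FPKM in the GBP5 library, a 4.51-fold difference (log2 ratio 1.94, or 1.44 after rescaling). Other guanylate-binding protein genes were higher to a similar extent: Gbp2 had 33.8 and 179 FPKM, Gbp3 38.5 and 138 FPKM and Gbp7 16.1 and 58.8 FPKM. Of the 11 family members measured, 10 were at least 2-fold higher and none was lower, before and after rescaling, and Gbp5 ranked 5 of 11 by FPKM ratio. Gbp2b had the highest ratio, 9.65-fold (interval 8.53 to 10.9, from 286 and 2579 reads), and Gbp8 was 5.83-fold higher. Gbp10 was the exception, at 23.2 FPKM in the β-Gal library and 23.3 in the GBP5 library, which became a log2 ratio of -0.50 after rescaling. Members of this family resemble each other closely, so reads may be split between them with some uncertainty.

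**Figure D2:**
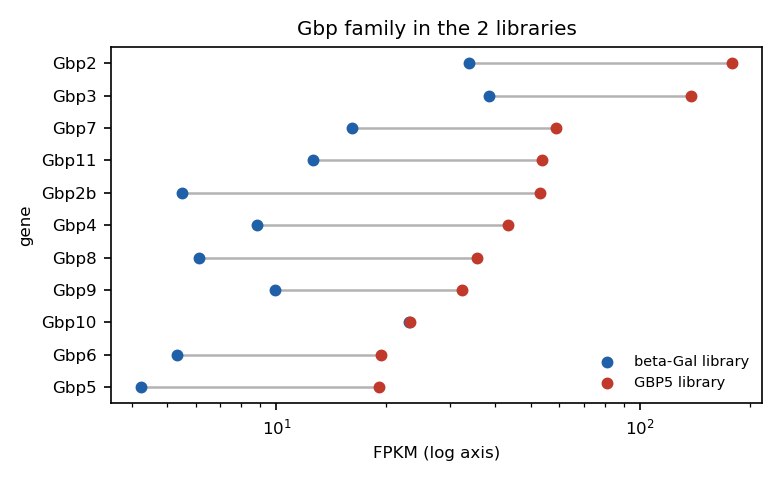
FPKM of the 11 members of the Gbp family on a log axis, in the β-Gal library (blue) and the GBP5 library (red), 1 library each, with a grey line joining the 2 values of a gene. Gbp5 went from 4.24 to 19.1 FPKM, and 10 of 11 members were at least 2-fold higher, also after rescaling; Gbp10 had nearly the same value in both and a log2 ratio of -0.50 after rescaling.

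Interferon-inducible genes were higher as a group. Among 29 measured interferon-gamma-inducible genes, 25 were at least 2-fold higher and none lower (16 and 1 after rescaling), with a median log2 ratio of 1.62. The largest log2 ratios with the pseudocount were those of Ubd, which encodes the ubiquitin-like modifier FAT10, at 10.3 and 313 FPKM (30.3-fold, interval 26.1 to 35.4), of Tgtp2, a GTPase (9.49-fold, interval 8.54 to 10.6), and of H2-Eb1, an MHC class II chain (6.14-fold). The other MHC class II genes H2-Aa and H2-Ab1, named after their values were seen, were 3.54-fold and 3.09-fold higher. The MHC gene H2-K1, also named after its value was seen, went the other way, at 2243 and 1525 FPKM. It was the member lower after rescaling, with a log2 ratio of -1.09, and H2-D1 and B2m did not pass 2-fold. For the MHC genes, a strain difference between the libraries, a candidate raised below, could not be told apart from an effect of the virus. Of 28 type I interferon-inducible genes, 18 were higher and none lower (12 and 0 after rescaling), with a median of 1.37. Rsad2, which encodes the antiviral enzyme viperin, went from 6.99 to 36.0 FPKM, Oasl2 from 13.3 to 57.6 FPKM and Mx1, an antiviral GTPase, from 1.92 to 10.1 FPKM.

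Cytokine and chemokine genes were higher in part. Of 20 measured, 9 were at least 2-fold higher and 1 lower (5 and 1 after rescaling), with a median of 0.96. The monocyte-attracting chemokine gene Ccl2 was at 2.45 and 15.8 FPKM, and Ccl3 and Ccl4 were 5.65-fold (interval 3.39 to 9.93) and 4.99-fold (interval 2.83 to 9.39) higher, from 18 and 15 reads in the β-Gal library. Tnf was 3.40-fold higher (interval 1.94 to 6.25, from 17 and 54 reads), with a log2 ratio of 0.92, short of the size rule with a pseudocount of 1 FPKM but 1.61 with 0.1 FPKM. Il1b was at 4.17 and 5.04 FPKM, a ratio of 1.21 with an interval of 0.846 to 1.73, and Il6 had 1 and 4 reads, a ratio of 4.28 with an interval of 0.423 to 211, so no difference was detectable at this depth for either. After rescaling, the log2 ratios of Tnf and Il1b became 0.59 and -0.21. Cxcl1, a neutrophil-attracting chemokine named after its value was seen, was the lower member, at 44.0 and 15.1 FPKM. With a stricter filter of 5 FPKM this list no longer stood apart from random lists.

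Inflammasome genes, which encode sensors and enzymes of pyroptotic cell death, had 6 of 16 measured members higher and 1 lower (1 and 1 after rescaling), with a median of 0.95. Nlrp3, an inflammasome sensor, was at 0.906 and 3.78 FPKM, and Casp1, the caspase that cleaves interleukin-1β, was 3.07-fold higher (interval 2.60 to 3.64); after rescaling their log2 ratios were 0.92 and 0.99. Naip2 was 3.56-fold higher and Nlrp6 was 3.62-fold lower. Genes of NF-kappaB feedback and adhesion were higher in 6 of 18 cases and lower in none (1 and 1 after rescaling, median 0.86), and that list too lost its distance from random lists at 5 FPKM. Vcam1, which binds leukocytes to vessels, was at 12.6 and 104 FPKM, Tnfaip3, an inhibitor of NF-kappaB, was 3.18-fold higher and Tlr4, the endotoxin receptor, 2.77-fold, and the log2 ratios of the last pair were 0.96 and 0.80 after rescaling.

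Genes of apoptosis and death receptors were higher in 13 of 25 cases and lower in none (10 and 0 after rescaling, median 1.06 as deposited). The TWEAK receptor gene Tnfrsf12a was at 8.59 and 145 FPKM, the cell cycle inhibitor Cdkn1a at 22.1 and 338 FPKM, and Cidec, which encodes a lipid droplet protein, was 15.6-fold higher (interval 12.6 to 19.5).

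Acute-phase proteins, which hepatocytes secrete in inflammation, were mostly lower with GBP5. Of 25 measured, 14 were at least 2-fold lower, 1 was higher and 10 were neither (16 lower and 1 higher after rescaling), with a median of -1.03. Saa1 was at 2603 FPKM in the β-Gal library and 373 in the GBP5 library, and Saa2 at 1627 and 232 FPKM. Saa3, a serum amyloid A gene that macrophages also express, was the higher member, at 104 and 911 FPKM. Saa1 and Saa2 are near-identical copies, so the split between them is uncertain. Neutrophil markers were lower as well: 13 of 14 were at least 2-fold lower and none higher, also after rescaling, with a median of -2.17. Lactoferrin (Ltf) was 15.9-fold lower, with 2204 and 130 reads, neutrophilic granule protein (Ngp) 10.4-fold lower, and S100a8, a calcium-binding protein abundant in neutrophils, was at 840.2 and 88.1 FPKM. B and plasma cell markers were lower in 4 of 8 cases and higher in none (5 and 0 after rescaling, median -1.12 as deposited), with Igkc, the kappa light chain constant region, 9.01-fold lower, Jchain 6.03-fold lower (471 and 73 reads) and Mzb1 5.70-fold lower. The β-Gal library, in which these groups were higher, was also the library with pancreatic transcripts. Its listed acinar genes held 0.157% of FPKM, against 0.264% in neutrophil and 3.47% in acute-phase genes, and no link was tested.

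T and NK cell markers were higher in 17 of 22 cases and lower in none (8 and 0 after rescaling), with a median of 1.26. The cytotoxic granule protease gene Gzmb was at 10.5 and 44.7 FPKM, the costimulatory receptor Cd28 at 0.936 and 5.65 FPKM, and the NK cell receptor Klrk1 was 4.12-fold higher (interval 3.34 to 5.13). Macrophage, Kupffer cell and monocyte markers were mixed, with 8 of 20 higher and 1 lower, but 3 higher and 2 lower after rescaling (median 0.79, or 0.27 rescaled). Gpnmb, a glycoprotein of lipid-laden macrophages, was at 1.73 and 29.5 FPKM and Mpeg1, a pore-forming macrophage protein, at 76.7 and 229 FPKM, whereas the Kupffer cell receptor Vsig4 was 4.11-fold lower (189 and 43 reads). Of 6 dendritic cell markers, 3 were higher and none lower, before and after rescaling: Itgax (5.64-fold), Clec9a (4.24-fold) and Batf3 (4.34-fold).

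Cholangiocyte markers were higher in 4 of 11 cases and lower in 1 (3 and 1 after rescaling), and their median of 0.30, -0.04 after rescaling, lay within random lists. With a filter of 5 FPKM, and fewer members, that median was 1.37 and stood apart from random lists. The members that were higher included Krt8 (134 and 669 FPKM) and Krt18 (98.4 and 359 FPKM), keratins that hepatocytes also express, and Krt23, 12.0-fold higher from 9 and 101 reads (interval 6.08 to 27.0). Sinusoidal endothelial markers had 2 of 15 members higher and none lower, but none higher and 1 lower after rescaling, with a median of 0.24 that became -0.28. Lyve1 was 2.54-fold higher, Dnase1l3 2.15-fold (interval 1.98 to 2.34) and Pecam1 1.90-fold; the log2 ratios of the first pair were 0.76 and 0.55 after rescaling. Stellate cell and matrix genes were higher in 9 of 21 cases and lower in none (5 and 0 after rescaling, median 0.92 as deposited). Collagen Col1a1 was at 5.64 and 23.7 FPKM, and the matrix metalloproteinases Mmp12 and Mmp13 were 13.3-fold and 11.9-fold higher.

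Hepatocyte genes were lower in part. Of 28 hepatocyte identity and plasma protein genes, 16 were at least 2-fold lower and none higher (22 and 0 after rescaling), with a median of -1.06. Alb was at 74174 and 43416 FPKM, a log2 ratio of -0.77 that became -1.31 after rescaling. Hpd, an enzyme of tyrosine breakdown, was 8.65-fold lower, and Vtn, which encodes the plasma protein vitronectin, was 3.29-fold lower. Xenobiotic cytochrome P450 genes were lower in 13 of 22 cases and higher in 3 (15 and 2 after rescaling), with a median of -1.12. Cyp2c50 was at 322 and 12.0 FPKM and its close paralogue Cyp2c54 at 129 and 1.58 FPKM, whereas Cyp2a4 was 9.12-fold higher (interval 8.53 to 9.75). Bile acid genes were lower in 7 of 19 cases and higher in 2 (10 and 2 after rescaling, median -0.50 as deposited). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 6.94-fold lower, with 5373 and 724 reads, and Cyp8b1, which makes cholic acid, 8.93-fold lower, with 2903 and 304 reads. The uptake transporters Slco1a1 and Slc10a1 were 21.2-fold and 9.18-fold lower.

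Lipid synthesis and glucose metabolism lists had medians below random lists, although most of their members did not pass 2-fold as deposited. Of 19 genes of fatty acid and triglyceride synthesis, 7 were lower and none higher (14 and 0 after rescaling), with a median of -0.73. Thrsp, a regulator of lipogenesis, was at 473 and 56.6 FPKM, the fatty acid elongase Elovl6 at 167 and 29.3 FPKM and the desaturase Scd1 at 1490 and 329 FPKM. Cholesterol synthesis genes were lower in 7 of 22 cases and higher in none (15 and 0 after rescaling, median -0.68 as deposited), with Insig1 3.25-fold, Fdps 4.11-fold (132 and 30 reads) and Sc5d 2.86-fold lower. Glucose metabolism genes were lower in 6 of 19 cases and higher in 2 (8 and 1 after rescaling, median -0.37 as deposited). The gluconeogenic enzymes Pck1 and G6pc were at 718 and 141 FPKM and at 101 and 25.3 FPKM, and the glycolytic enzyme Pklr was 5.22-fold lower. Fatty acid oxidation genes and PPAR-alpha targets went both ways, with 11 of 26 higher and 2 lower, or 7 and 5 after rescaling, and their median of 0.57 lay within random lists. Higher members were Acot2, an acyl-CoA thioesterase (11.2-fold, interval 9.57 to 13.2), Pdk4, which restrains glucose oxidation (11.2-fold), and the fatty acid receptor Cd36 (4.43-fold, interval 4.23 to 4.65).

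Cell cycle genes showed the highest median of the lists in the plot of list medians. Of 28 measured, 27 were at least 2-fold higher and none lower, against 26 and none after rescaling, with a median log2 ratio of 2.19. Ccne1 and Ccne2, cyclins of S phase entry, were 7.99-fold and 8.72-fold higher, and the mitotic kinase Aurka was 7.14-fold higher (interval 5.97 to 8.60). Oxidative stress genes were higher in 14 of 21 cases and lower in none (12 and 2 after rescaling, median 1.67 as deposited). The glutathione S-transferases Gsta1 and Gstm3 were at 27.5 and 1025 FPKM and at 68.7 and 1173 FPKM, ratios of 37.2 (interval 33.6 to 41.2) and 17.1 (interval 16.3 to 18.0). Srxn1, which reactivates peroxiredoxins, was 16.7-fold higher. Both transferases belong to families of close paralogues, which adds uncertainty to their reads. Unfolded protein response genes mostly did not pass 2-fold: 2 of 21 were higher and none lower, but 6 were lower after rescaling, and the median of 0.54, 0.03 rescaled, lay within random lists. The members past 2-fold were Atf3 (4.98-fold) and Trib3 (3.92-fold), stress-responsive regulators of transcription and signalling, while Pdia6 was 1.97-fold higher.

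**Figure D3:**
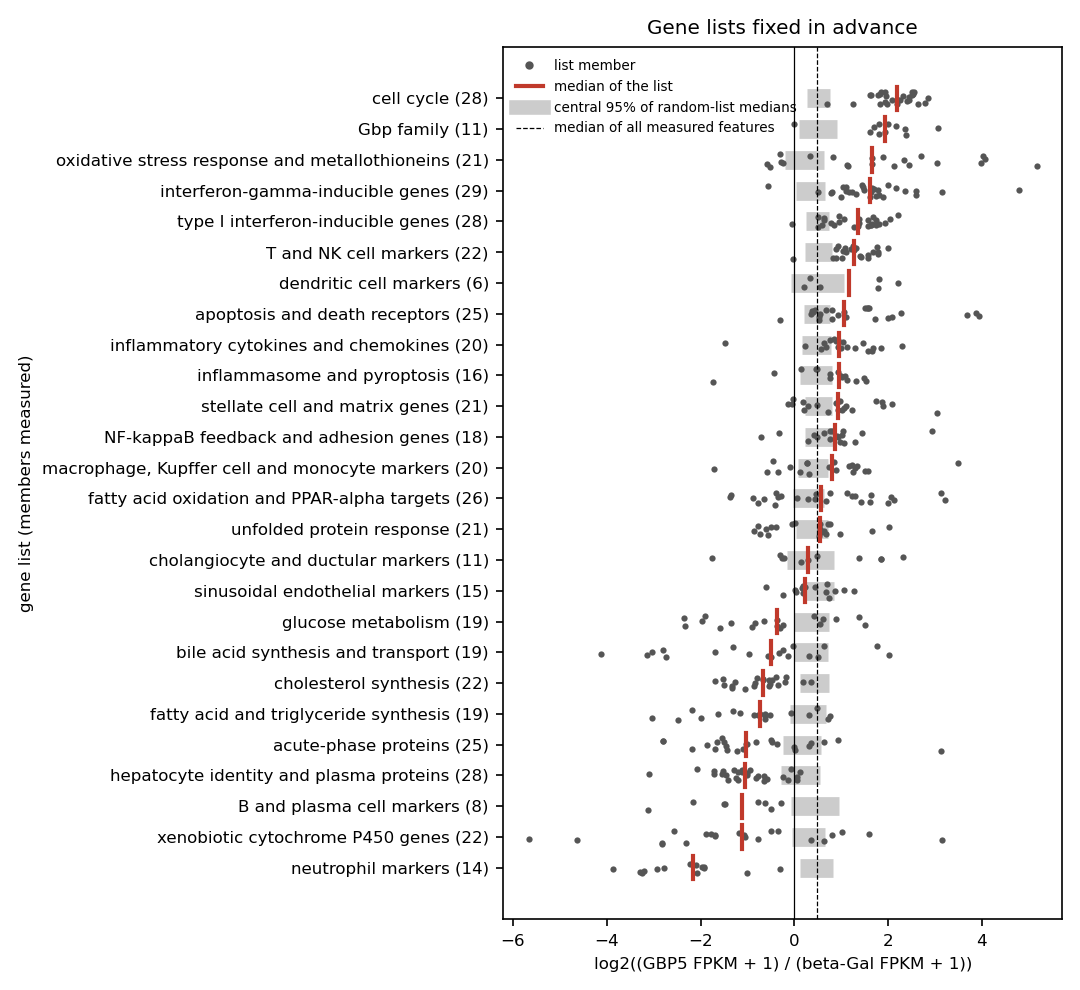
Log2((GBP5 FPKM + 1)/(β-Gal FPKM + 1)) of the members of each biology and cell type list (grey points, 1 library per group), with the median of the list (red bar) and the central 95% of medians of random lists (grey band). The dashed line is the median of all features, 0.48; the medians ran from -2.17 for neutrophil markers to 2.19 for cell cycle genes, and those of cholangiocyte and sinusoidal endothelial markers changed sign after rescaling.

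By log2 ratio with the pseudocount, the 8 highest genes were Sprr1a, a cornified envelope protein (441-fold, interval 151 to 2140, from 3 and 1236 reads), the carbonyl reductase Cbr3 (71.2-fold), Gsta1, Ifi202b, Ly6d (35.5-fold, interval 29.6 to 42.9), Eno1b, Tpm3-rs7 and Ubd. Ifi202b, an interferon-inducible gene, had 0 and 1014 reads and was 362-fold higher against a floor of 3 reads, with an exact 95% limit of 294-fold. This gene is known to be silent in C57BL/6 mice. A strain difference between the libraries, which was not tested, may account for its reads. Eno1b (0.0618 and 32.6 FPKM) and Tpm3-rs7 (0.0258 and 28.7 FPKM) are copies of other genes and their reads are uncertain. As deposited, all of the 8 lowest on that scale encode pancreatic products. Ctrb1 was at 372 FPKM in the β-Gal library and listed at 0 in the GBP5 library. Pnlip, Cpb1 and the insulin gene Ins2 were at 71.0, 70.1 and 69.4 FPKM and listed at 0. After rescaling, Smoc2, named after its value was seen, had a log2 ratio of -6.57, below Cela3b, Pnlip, Cpb1 and Ins2 (-6.35 to -6.14). The trypsinogen genes Try4 and Try5 had 2005 and 1899 reads in the β-Gal library and none in the GBP5 library. They were 625-fold and 592-fold lower against the floor of 3 reads, with exact 95% limits of 508-fold and 481-fold. Prss2 had 1678 and 1 reads, a β-Gal to GBP5 ratio of 1569, and Cela3b had 1770 and 6 reads, a ratio of 276.

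Lists kept as checks on the tissue and the animals also differed. All 12 pancreatic acinar genes were at least 2-fold lower with GBP5, also after rescaling, and they held 0.157% of FPKM in the β-Gal library and 0.002% in the GBP5 library. Male-biased liver genes were lower in 11 of 18 cases and higher in 1 (13 and 1 after rescaling). Serpina1e was 25.3-fold lower and Hsd3b5, with 599 and 0 reads, 187-fold lower against the floor of 3 reads (exact limit 151-fold). Female-biased genes were lower in 4 of 10 cases and higher in 1 (5 and 1 after rescaling), with Cux2 at 6.95 and 0.132 FPKM and Cyp2a4 the higher member. Circadian genes were lower in 3 of 19 cases and higher in 1 (8 and 0 after rescaling), with the clock output gene Dbp 5.07-fold lower. Immediate early genes were higher in 8 of 13 cases and lower in none (6 and 0 after rescaling), led by Klf6 (5.35-fold) and Gadd45b (5.30-fold). Of 10 erythroid genes, 1 was higher, Slc4a1 (6.70-fold), and 1 lower, Alas2 (3.35-fold), with 1 and 2 after rescaling. Mitochondrially encoded genes had 1 of 12 members lower, mt-Atp8 with 59 and 21 reads, and 3 lower after rescaling, among them mt-Nd2 (4939 and 2795 FPKM). None of 40 cytosolic ribosomal protein genes passed 2-fold as deposited and 1 was lower after rescaling; their median of 0.54, 0.005 when rescaled, lay above random lists matched on expression (upper limit 0.46). As deposited, Rpl19 (1.68-fold) and Rps20 (1.67-fold, interval 1.60 to 1.73) were the farthest from parity.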

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

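Rescaling by ribosomal protein genes and counting without pseudogenes were chosen after the data were seen, and the other settings before. Rescaling the GBP5 library by the median ratio gave 958 higher and 1276 lower, and by ribosomal protein genes 953 and 1283, against 2605 and 756 as deposited, which is what dividing the GBP5 library by a single factor does to ratios that mostly lie above parity. A pseudocount of 5 FPKM gave 1101 and 435, since it shrinks the ratios of low genes. The other 7 settings stayed within 1.5 times the deposited counts, from 1922 to 3606 higher and from 536 to 946 lower. Of these, dropping the filter could not change the counts, since the size rule with its pseudocount already requires 1 FPKM in a library. With a filter of 5 FPKM the medians of cytokine and chemokine genes (1.02) and of NF-kappaB genes (0.84) no longer stood apart from random lists and that of cholangiocyte markers (1.37) did, with fewer members each; the cause was not tested further. All 34 lists kept their call with a pseudocount of 0.1 FPKM; they also did under the median ratio and TPM, but a single factor moves a list and its random lists nearly alike, so that says little about stability. Among 155 named genes, rescaling took the log2 ratio with the pseudocount of 9 below the size rule, brought 2 past it and changed the sign of 3 small ratios, and a pseudocount of 0.1 FPKM brought 2 past it. No paired analysis was possible because each group had 1 library, and no library could be left out. Depth limits genes of a few reads, such as Il6.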

Other observations

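Except for the comparison of islet genes and that of pseudogenes with 10 to 49 reads, the lists and tests in this part were chosen after the result was seen. Further gene groups separated the livers. Of 14 p53 target genes, 11 were at least 2-fold higher with GBP5 and none lower (7 and 0 after rescaling), with a median log2 ratio of 1.49. Cdkn1a led them, and it, Mdm2, Trp53inp1 and Bbc3 are also in the apoptosis list, so these lists overlap. Ccng1 was 3.18-fold higher (interval 2.99 to 3.39) and Mdm2, the ubiquitin ligase that degrades p53, 2.98-fold. Genes of the fetal liver were higher in 5 of 6 measured cases (3 after rescaling) and lower in none, with alpha-fetoprotein (Afp) at 4.88 and 43.8 FPKM, the imprinted RNA H19 at 1.97 and 40.3 FPKM and Gpc3 8.88-fold higher (interval 5.57 to 14.9). Cytoskeleton genes were higher in 15 of 16 cases (11 after rescaling) and lower in none, with a median of 1.87: Actb was at 955 and 3211 FPKM, Vim at 60.4 and 230.2 FPKM and the annexin Anxa2 5.42-fold higher. Proteasome subunits had a median of 0.77, above random lists, but 2 of 22 passed 2-fold and none did after rescaling.

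Among genes outside the naming rule, the glutathione precursor transporter Slc7a11 was at 0.0908 and 16.2 FPKM and Gclc, which makes the glutathione precursor, at 60.4 and 506 FPKM. Liver genes that were far lower included Smoc2 (472 and 5.75 FPKM), Sult2a8 (50.2-fold), Inmt (28.3-fold, 17776 and 587 reads) and Gnmt (10.5-fold), a methyltransferase of methionine metabolism. The Y-linked genes Ddx3y (32.4 and 42.0 FPKM) and Eif2s3y (53.3 and 52.4 FPKM) were present in both libraries and Xist was at 0.0174 and 0.0558 FPKM.

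Mouse Gbp5 was at 19.1 FPKM in the library of the GBP5 virus. It ranked 5 of the 11 family members by FPKM ratio, so its level does not single out reads of the injected insert, and a part from the insert cannot be told apart from the endogenous gene. Of the other 10 members, 9 were at least 2-fold higher, with a median FPKM ratio of 3.95, so Gbp5 may have been raised together with its family. The insert may also come from another species, with reads that do not align to mouse Gbp5: the fragments in the labels end at residue 586, and none of the 3 annotated mouse proteins has that length, the nearest having 590 residues. That length test concerns the species alone, and the sequence of the insert was not used here.

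Some features had reads in the GBP5 library only, and they include genes known to be silent in C57BL/6 mice, H2-Ea-ps (listed at 0 and 252.9 FPKM) and Ifi202b (0 and 1014 reads). Of processed pseudogenes with at least 50 reads in a library and at most 1 in the other, 9 lay on the GBP5 side and 0 on the β-Gal side. A constant leak of reads from a parent gene would give the copy the ratio of its parent. It is argued against for 5 copies whose symbol names the parent. Relative to a floor of 3 reads, each copy's ratio was at least 17.3 times that of its parent. Hmga1b, for example, had 0 and 281 reads, and its parent Hmga1 was 2.93-fold higher. The copies were picked after their own reads were seen, so the size of that multiple partly follows from the choice. The ratios of the parents ran from 1.26 to 2.93. An animal of another genetic background, or an outside sample, in the GBP5 library is a candidate explanation. A separate set had 10 to 49 reads in a library and none in the other. There, 85.7% of processed pseudogenes (6 of 7) lay on the GBP5 side, but so did 49 of 74 protein-coding genes. With so few pseudogenes, that set cannot decide for or against the explanation. It stays open whether H2-Ea-ps and Ifi202b were induced, but their ratios against the floor exceeded that of every listed interferon-inducible gene. In the β-Gal library, the class II genes H2-Aa, H2-Ab1 and H2-Eb1 were at 72.2, 134.7 and 61.0 FPKM and H2-Ea-ps at 0. Those class II genes were 3.54-fold, 3.09-fold and 6.14-fold higher with GBP5. Against a floor of 3 reads, which is not a confidence limit, the Ifi202b ratio was 11.9 times that of Ubd. The exact 95% limit of Ifi202b was 294-fold, against a ratio of 30.3 for Ubd. The H2-Ea-ps value against 3 reads was 1337, from a read number that was not whole. However, Sprr1a, which is in neither interferon list, had a ratio of 441 from 3 β-Gal reads with an interval up to 2140. The genotypes and an effect of the virus itself were not tested.

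Pancreatic transcripts were present in the β-Gal library: the acinar genes took 0.101% of its reads and 0.0009% of those of the GBP5 library. Pancreatic tissue carried over into the liver sample may account for this, as 9 of 10 islet genes, of which only Ppy reached 1 FPKM (3.08 FPKM, and listed at 0 with GBP5), also had more FPKM in the β-Gal library, and the endocrine genes Ins1 and Iapp were at 12.5 and 5.75 FPKM there and listed at 0 with GBP5. Reads of a pancreas library assigned to the β-Gal library, at that 0.101%, cannot be told apart from carried-over tissue, since no such library was used here. No biological explanation was tested.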
